A study of Mus musculus with 16 samples.

How the data were processed

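RAW264.7 mouse macrophage-like cells were stimulated with 100 ng/ml lipopolysaccharide (LPS, a bacterial cell wall component), and ribosome footprints and input RNA were sequenced from untreated cells and after 15, 30, 45, 60, 75 and 90 min and 16 h, per the labels. About 10% of each lysate was saved as input before digestion, so the input and footprint libraries of a time point came from the same lysate, per the labels' protocols. Cells were washed and lysed with cycloheximide, lysates were digested with RNase I, and footprints were taken from the monosomal fractions of a sucrose gradient, per the labels' protocols. The input was cytoplasmic RNA fragmented by alkaline hydrolysis, and both materials were depleted of ribosomal RNA and size-selected at 25 to 35 nt, per the labels' protocols. There were 16 libraries in 16 groups, with 1 library per combination of material and time point.

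The series holds 1 table of 13832 genes. Of its columns, 16 hold whole-number read counts per gene as deposited by the authors, and 16 hold the same counts divided by a size factor, a normalised signal per library that the authors labelled as DESeq2-normalised, per the file headers. Within each normalised column the ratio of count to signal was constant to 5.8e-15, and it matched the median-of-ratios size factor computed over all 16 libraries to 4.4e-16. Bowtie 0.12.8, DESeq2 1.18.1 and the mm10 genome build are named in the submitters' processing notes. The way reads were counted, the features they were counted over, the treatment of strand and of reads with several matches, and any removal of duplicate reads are not given in the sources used here. The deposited counts summed to 6702930 to 6702932 in every library. Rounding of scaled values would miss a common total by about 33, so the values have the form of reads drawn to a common number; that step is not given in the sources used here. Equal totals carry no information on the original sequencing depth. The deposited normalised signal was used only for this check.

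Tests were run on the deposited counts. Genes with at least 10 counts in at least 4 of the 8 input and at least 4 of the 8 footprint libraries were kept, which left 9529. Libraries were scaled by TMM factors and fitted with edgeR 4.0.16 (quasi-likelihood F-test, glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Every adjusted p for a gene comes from that test unless DESeq2 is named. Input and footprints were each fitted with a linear and a quadratic term in minutes over 0 to 90 min and a separate term for 16 h. The change over 0 to 90 min was a joint test of the linear and quadratic terms, and its size is the largest excursion of the fitted curve from its value at 0 min. The change at 16 h was the test of the 16 h term against the fitted value at 0 min. Ribosome density, the ratio of footprints to input, was tested in a model over all 16 libraries with the time point as a block and interactions of material with the time terms. A further model with time point and material gave the mean density level of each gene relative to the typical gene. The time-course and density-change models had 4 residual degrees of freedom and the level model 7. With 1 library per group, the error is the scatter of libraries about a smooth curve, and the lone 16 h library was assumed to vary like the others. No difference between single libraries has a replicate check. Untreated cells were sampled only at 0 min, with no untreated culture at later times. Effects of LPS therefore cannot be told apart from those of handling or time in culture. Intervals for ratios of single libraries are 95% intervals from counts; no use of molecular identifiers is given in the sources used here, so intervals and floors cover counting error only. A ratio against a count of 0 was computed against a floor of 3 counts in that library and is written as a lower bound.

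Gene lists were fixed before the data were examined. They covered immediate early genes, LPS feedback regulators, cytokines, chemokines, interferon-stimulated genes, late effectors of macrophage activation, ribosomal proteins, other TOP mRNAs (translation-factor and related mRNAs that start with a 5′ terminal oligopyrimidine tract), nuclear-encoded oxidative phosphorylation genes, mitochondrially encoded genes and replication-dependent histones. Further lists covered ATF4 targets, endoplasmic reticulum chaperones, heat shock genes, cholesterol synthesis, cell cycle, glycolysis, macrophage identity genes, and markers of osteoclasts, fibroblasts, epithelium and lymphocytes, and noncoding RNAs. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, again with the correlation estimated, and with fry, adjusted over all lists and contrasts. The contrasts were the fitted value at 90 min against 0 min and the 16 h term, for input, footprints and density. Camera compares a list with the other genes. The PValue of fry tests whether a list's genes move, on balance, 1 way, and its Mixed value whether they change in either direction. Median changes of a list in single libraries were placed among 10000 random lists of the same size matched on mean expression. Counts of changed members are given over all genes and "adjusted over the list alone".

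Named genes were chosen by a rule made before the data were examined. For each comparison it took the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 50 counts, predicted genes and clone names skipped, up to 4 members of each list with the largest changes, and always Tnf, Nfkbia, Nfkbid, Nfkbiz, Ier3, Zfp36, Dusp1, Actb and Gapdh. Some genes that the rule chose are not reported here. Genes named outside the rule are identified as such.

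The procedure was tested on simulated data, in which counts of the 9529 genes were drawn with known changes. Changed genes had a mean of at least 50 counts. Within 90 min they moved steadily on the log2 scale, a shape the fitted curve can take. Scatter followed the dispersion trend, with no excess for single genes or lysates. The shares below therefore do not cover sharp peaks or weakly expressed genes. Changes of 1.5-fold, 2-fold and 4-fold were recovered for 56.7%, 92.5% and 100% of genes in the input time course, for 41.8%, 94% and 100% in the footprint time course, and for 17.9%, 73.1% and 98.5% in the density time course. At 16 h the shares were 44.8%, 94% and 100% for input, 37.3%, 92.5% and 100% for footprints, and 23.9%, 68.7% and 98.5% for density. The level test recovered 100% at each size. Of all calls on simulated data, 4.31% to 9.35% were false, depending on the comparison.

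Alternatives were RLE size factors, other filters on low counts, library sizes without mitochondrially encoded and the 20 most abundant genes, DESeq2 1.42.0, other time terms, no time-point block, a 1.5-fold minimum for the level, and leaving out single time points. For the 16 h comparisons only time points from 15 to 90 min were left out, so the weight of the untreated libraries on them was not tested. Scaling by the total counts of the tested genes without TMM and a cubic curve were added after the data were seen. Genes were matched by symbol to GENCODE release M21 (GRCm38, the assembly of mm10), and 9130 of the 9529 tested genes had a match. Coordinates, coding lengths and the share of coding 29-mers found in no other annotated transcript come from that annotation. Python 3.11.15 and matplotlib 3.10.9 were used for annotation and plots. Genes under the count filter were left out of the tests.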

Results

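Ribosome footprints and cytoplasmic input RNA were counted per gene in RAW264.7 cells, a mouse macrophage-like line, before and after exposure to 100 ng/ml lipopolysaccharide (LPS). The 16 libraries formed 16 groups of 1 library, 8 of input and 8 of footprints, at 0, 15, 30, 45, 60, 75 and 90 min and at 16 h. Each library held between 6702930 and 6702932 counts, and 9529 of 13832 genes passed the count filter. No group had a replicate, so each ratio of single libraries below has no replicate check, and the tests rest on the scatter of the libraries about a smooth curve. Adjusted p-values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless DESeq2 is named, and changes are relative to the typical gene.

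The first comparison asked which cytoplasmic mRNAs changed within 90 min of LPS. No untreated culture was sampled after 0 min, so handling and time in culture cannot be told apart from LPS. Transcripts of the inflammatory cytokines Il1b and Il1a rose to 464-fold (95% counting interval 235 to 1080) and 137-fold (58.2 to 422) of untreated at 90 min, with adjusted p-values of 0.00041 and 1.8e-05. The chemokine Cxcl10 rose to 352-fold (170 to 876; adjusted p = 1.4e-11), and Acod1, whose enzyme makes itaconate, to 160-fold (112 to 238; adjusted p = 0.0028). Tnf stood at 66.8-fold of untreated at 45 min, Zfp36, which encodes a protein that destabilises cytokine mRNAs, at 59.1-fold, and the NF-κB inhibitor Nfkbia at 16.2-fold. Tnf, Zfp36, Nfkbia, Nfkbid, Ier3 and Dusp1 did not pass the test, with adjusted p-values of 0.11, 0.092, 0.09, 0.056, 0.059 and 0.068; DESeq2 called all 6 (0.0014, 3e-04, 0.00089, 0.00012, 8e-06 and 8.3e-06), and a cubic curve gave 0.043 for Dusp1. All 7 chemokine genes rose, as did 8 of 11 cytokine genes, 15 of 23 LPS feedback regulators, 13 of 20 immediate early genes and 11 of 14 late effectors; 2 immediate early genes and 1 cytokine gene fell. Adjusted over the list alone, the rises numbered 7, 9, 22, 17 and 11. Transcripts of Fam212a, of the repressor Bhlhe41, of the transcription factor Klf10 and of the MAP kinase phosphatase Dusp6 fell to 16.1-fold, 8.76-fold, 8.27-fold and 7.66-fold below untreated, with adjusted p-values of 6.5e-08, 1.8e-05, 3.6e-05 and 0.00028. With the square root of time those 4 calls were lost (0.094, 0.18, 0.11 and 0.12).

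Over all genes, 1448 rose and 1131 fell in input, 2579 together, and 1694 were called without the 90 min library. With scaling by total counts the balance turned, to 1007 up and 1991 down. Of 18 ATF4 targets, genes of the amino acid and stress response, 12 rose, also adjusted over the list alone, led by Chac1 (2.80 ± 0.24 on the log2 scale, adjusted p = 2.4e-06) and Sesn2 (2.03 ± 0.15, adjusted p = 5.8e-07). Of 23 cholesterol synthesis genes, 13 rose, or 14 adjusted over the list alone. Replication-dependent histone mRNAs fell in 41 of 53 cases, or 44 adjusted over the list alone, with a median change of -0.62. The camera test gave adjusted p-values of 2.3e-07, 3.2e-06 and 1.3e-08 for those 3 lists, and 0.038, 0.3 and 0.54 with an estimated correlation. Of 25 macrophage identity genes 6 rose and 4 fell: the lipoprotein receptor Tlr2 (3.11 ± 0.21, adjusted p = 0.00084) and the LPS co-receptor Cd14 (1.82 ± 0.15, adjusted p = 0.00042) rose, and the lineage factor Cebpa fell (-1.76 ± 0.24, adjusted p = 0.00024). Of the control genes, Actb rose (0.82 ± 0.068, adjusted p = 5.3e-06), and Gapdh stood at -0.04 ± 0.076 (adjusted p = 0.84), with a sign that changed when the 15 min or the 60 min library was left out (0.04 each).

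**Figure D1:**
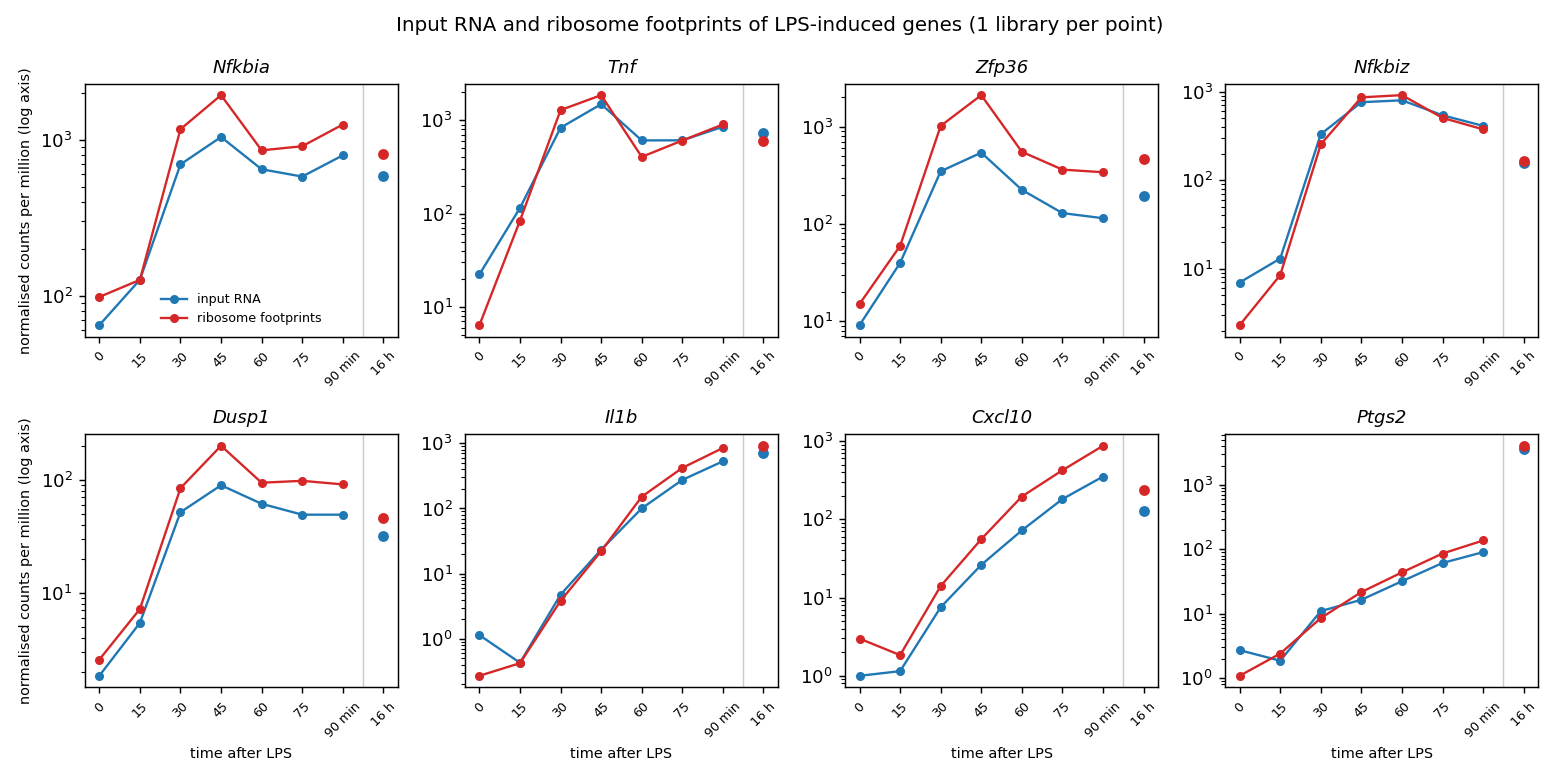
Normalised CPM (log axis) of 8 LPS-induced genes against time after LPS, in input and in footprints, with 1 library per point. Nfkbia, Tnf and Zfp36 were highest at 45 min in both materials, and Il1b had reached 464-fold of untreated in input at 90 min.

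The same question was asked of footprints, which count the ribosomes on each mRNA. Footprints on Il1b reached 3130-fold of untreated (865 to 25800, on 2 untreated counts; adjusted p = 4.5e-06), on Cxcl10 291-fold (192 to 465; adjusted p = 0.002) and on Il1a at least 348-fold against a floor of 3 counts (adjusted p = 1.7e-14) at 90 min. The footprints of Ptgs2, which encodes the inducible cyclooxygenase, rose to 126-fold (adjusted p = 2.4e-14). Tnf stood at 292-fold (219 to 397) at 45 min, Zfp36 at 140-fold (116 to 170) and Nfkbia at 19.8-fold (18.4 to 21.4), with adjusted p-values of 0.24, 0.14 and 0.18. Footprints of Dusp1 stood at 77.3-fold and of Ier3 at 41-fold, with adjusted p-values of 0.095 and 0.12. DESeq2 called these 5 (0.029, 0.0023, 0.024, 5.3e-05 and 0.00096). By list, 6 of 7 chemokine, 7 of 11 cytokine, 16 of 23 LPS feedback, 11 of 20 immediate early and 11 of 14 late effector genes rose, and 2 immediate early genes and 1 cytokine gene fell. Adjusted over the list alone, the rises numbered 7, 7, 22, 16 and 12. Falls included Fam212a (-4.74 ± 0.44, adjusted p = 2.6e-07) and Klf10 (-4.40 ± 0.38, adjusted p = 4.6e-07), calls lost with the square root of time (0.1 and 0.15).

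In all, 1207 genes rose and 870 fell in footprints, 2077 together, with a range of 1395 to 2540 on leaving out single time points. With scaling by total counts the balance turned, to 723 up and 2818 down. In both materials 841 genes rose and 553 fell; input and footprints of a time point come from the same lysate, so scatter between lysates is shared. Across 8384 genes, which are not independent replicates, the changes of footprints and input correlated at r = 0.12 at 15 min, 0.57 at 30 min and 0.86 at 90 min. By rank (Spearman) the correlations at those times were lower, at 0.11, 0.17 and 0.64. The inducible NF-κB regulator Nfkbiz rose in input (114-fold at 60 min, adjusted p = 0.033) and in footprints (397-fold, adjusted p = 0.026). Its call in input was lost without the untreated, 45, 60, 75 or 90 min library (adjusted p from 0.067 to 0.17), and in footprints without the untreated, 45, 60 or 75 min library (0.052 to 0.15). With a linear term and with the square root of time both calls were lost (0.28 and 0.13 in input, 0.35 and 0.17 in footprints), and with a cubic curve that in input (0.083). Footprints of Nfkbid rose to 35.3-fold at 45 min (adjusted p = 0.035), a call lost without the untreated, 15, 30, 60, 75 or 90 min library (0.054 to 0.14). On the log2 scale it stood at 5.20, against 1.79 with a linear term, 3.55 with the square root of time and 5.62 with a cubic curve, with the call lost in each (adjusted p = 0.72, 0.44 and 0.11).

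The series was designed to assess ribosome density, the ratio of footprints to input. Within 90 min, density rose on the mRNAs of the translation machinery itself. Of 72 ribosomal protein mRNAs, 67 rose and none fell, and 71 rose when adjusted over the list alone, with a median rise of 0.92 on the log2 scale. Rps19 rose by 1.21 ± 0.12 (adjusted p = 0.00011), Rplp2 by 1.27 ± 0.15 (adjusted p = 0.00028) and Rpl9 by 1.38 ± 0.18 (adjusted p = 0.00045). Of 24 other TOP mRNAs, which share the same 5′ tract, 12 rose and 16 adjusted over the list alone. The elongation factors Eef2 (1.44 ± 0.13, adjusted p = 2.8e-05) and Eef1a1 (1.28 ± 0.17, adjusted p = 0.00043) and the initiation factor subunit Eif3f (1.17 ± 0.12, adjusted p = 0.00011) were among them. Camera gave adjusted p-values of 5.8e-175 and 3e-38 for the lists, 0.046 and 0.052 with an estimated correlation, and fry 0.015 and 0.0085. Without the untreated pair none of the ribosomal protein mRNAs were called in density, the median excursion was 0.46, and none of the 6 mRNAs named kept its call; their values were 0.71, 0.63, 0.53, 0.70, 0.54 and 0.51 in the order given. With a linear time term 5 of these 6 lost their calls: Rplp2 (1.15, adjusted p = 0.15), Rpl9 (1.05, 0.42), Eef2 (1.22, 0.069), Eef1a1 (1.07, 0.078) and Eif3f (0.86, 0.34).

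Most of the density rise lay in the footprints. In input, 3 of the 72 ribosomal protein mRNAs fell and none rose, with no call adjusted over the list alone; 34 fell with scaling by total counts. The median ribosomal protein mRNA stood, in density, at 0.47 at 15 min, 0.89 at 30 min and 1.00 at 90 min relative to untreated on the log2 scale, above every matched random list at each of these times. Median footprints stood at 0.38, 0.62 and 0.83 at those times, and median input at -0.08, -0.24 and -0.14. Ribosomal protein genes took 6.49% of footprint counts in untreated cells and 9.66% at 75 min. In footprints 68 of the 72 rose and 1 fell, as 20 of the 24 other TOP mRNAs rose, among them Pabpc1 (1.72 ± 0.089, adjusted p = 1.3e-08), Tpt1 (1.41 ± 0.075, adjusted p = 1.6e-08) and Rpsa (0.99 ± 0.079, adjusted p = 1.3e-06). Adjusted over the list alone, 70 and 23 rose. Without the untreated library 55 of the ribosomal protein mRNAs still rose in footprints, and Tpt1 and Rpsa stood at 0.89 and 0.58. Of the 72 ribosomal protein genes, 28 had no 29-mer of coding sequence absent from all other transcripts, so reads may be shared with copies; the 13 members of both lists with at least 70% unique 29-mers included 8 that rose in density.

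**Figure D2:**
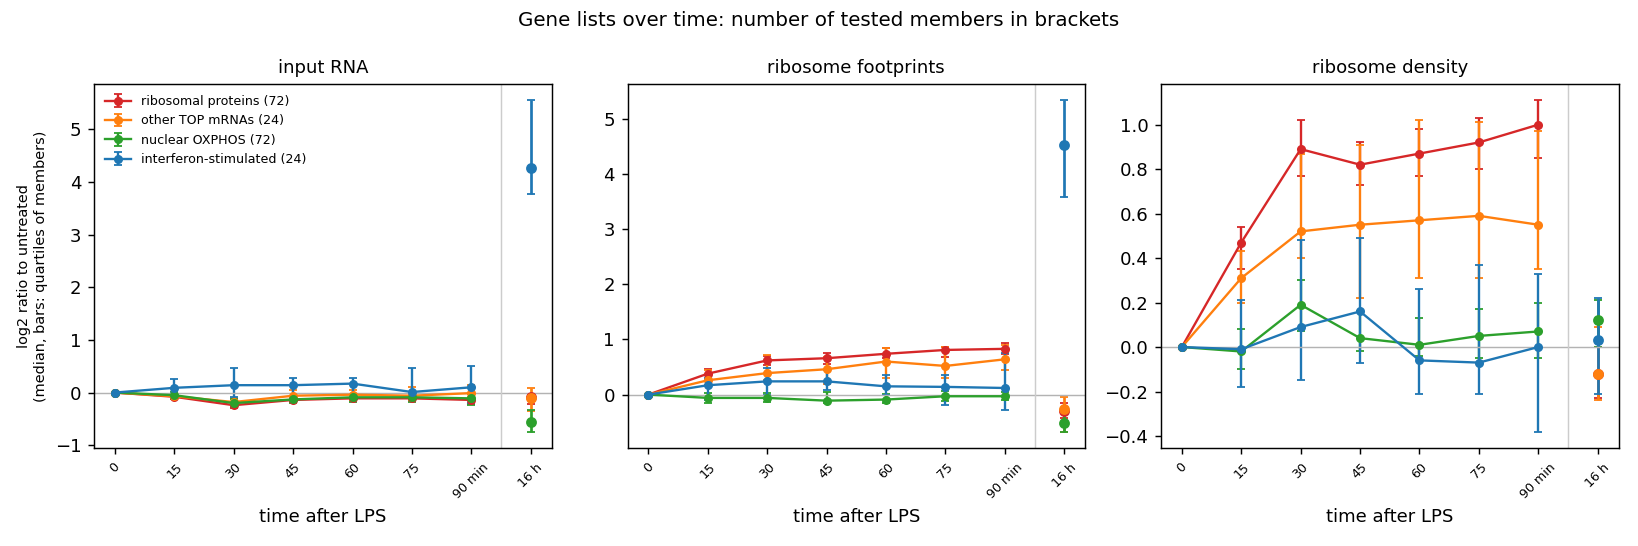
Median log2 ratio to the untreated library, with quartiles, against time after LPS for 72 ribosomal protein, 24 other TOP, 72 nuclear-encoded oxidative phosphorylation and 24 interferon-stimulated genes, in input, footprints and density. The ribosomal protein median in density rose to 1.00 at 90 min and stood at -0.12 at 16 h.

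Outside these lists, density rose within 90 min on some mRNAs of LPS feedback regulators and immediate early genes. Among the latter the orphan receptor Nr4a1 rose by 4.71 ± 0.61 (adjusted p = 0.00019), on 1 untreated footprint count. Of the feedback regulators, density rose on Zc3h12a, which encodes an RNase that degrades cytokine mRNAs (2.42 ± 0.5, adjusted p = 0.025), on the calcineurin inhibitor Rcan1 (1.67 ± 0.33, adjusted p = 0.014), on Nfkbiz (1.65 ± 0.28, adjusted p = 0.0037) and on Nfkbid (1.35 ± 0.21, adjusted p = 0.0018). Those 4 were the called members of the 23 feedback regulators, also adjusted over the list alone (camera adjusted p = 3.2e-09, and 0.046 with an estimated correlation). Falls were seen for the ferritin heavy chain Fth1 (-0.80 ± 0.15, adjusted p = 0.015), Vmp1 (-0.95 ± 0.14, adjusted p = 0.00089) and Ibtk (-0.93 ± 0.16, adjusted p = 0.005). Altogether 109 genes rose and 13 fell in density. Without the untreated pair 5 genes were called, and of the genes named here only Nr4a1 kept its call (2.55). Without the 30 min pair 328 were called, 184 up and 144 down, so the excess of rises was mostly lost. Scaling by total counts gave 93 up and 55 down. The calls of Zc3h12a (45, 60 or 75 min), Rcan1 (15 or 90 min) and Fth1 (15 min) were also lost without those pairs, at adjusted p-values of 0.077 to 0.2. Without the time-point block the calls of Nr4a1, Nfkbiz, Nfkbid and Zc3h12a were lost (adjusted p = 0.85, 0.98, 0.94 and 0.053), and with a linear time term they stood at 1.00, 0.50, 0.82 and 0.94 (adjusted p = 0.88, 0.75, 0.38 and 0.72). The call of Fth1 was also lost with a linear term (-0.75, adjusted p = 0.079), those of Nr4a1, Nfkbiz and Zc3h12a with the square root of time (adjusted p = 0.73, 0.51 and 0.53), and that of Zc3h12a with total counts (0.07).

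The comparison of 16 h with untreated cells addressed the late response. The untreated cells were those of 0 min, so changes at 16 h can come from LPS or from time in culture. Of the 38 genes on the interferon list, 24 passed the count filter, which leaves out genes with few counts until 16 h. Rsad2 was among those left out, with 5 untreated and 5612 counts at 16 h in input, and 1 and 5453 in footprints. All 24 tested genes rose in input and in footprints, also adjusted over the list alone, with medians of 4.28 and 4.40 on the log2 scale. Camera gave adjusted p-values of 1.2e-71 and 4.3e-85, and 0.013 and 0.011 with an estimated correlation. Within 90 min only 5 of the 24 had risen and 3 had fallen in input, and 6 and 3 in footprints. The ubiquitin-like Isg15 stood at 695-fold (297 to 2140) in input and 346-fold (236 to 530) in footprints, and Ifi44 at 138-fold (103 to 190) and 132-fold (106 to 167). All 14 late effectors rose in both materials, with Ptgs2 at 1350-fold (865 to 2240) and 3750-fold (1900 to 8680), and Acod1 at 807-fold (565 to 1200) and 1970-fold (1170 to 3600). The growth factor Csf3 stood at 1890-fold in input (523 to 15600, on 2 untreated counts) and at least 1590-fold in footprints. Of 11 cytokine genes 10 rose in input and 8 in footprints, or 10 and 9 adjusted over the list alone, and all 7 chemokine genes rose in both.

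Members of several other lists changed at 16 h. The glucose transporter Slc2a1 rose by 1.79 ± 0.1 in input (adjusted p = 4.4e-09) and 1.38 ± 0.26 in footprints (adjusted p = 0.0044), within a glycolysis list that was split (8 rose and 4 fell in input, 6 and 3 in footprints). Of 25 macrophage identity genes 12 rose and 6 fell in input, and 11 rose and 7 fell in footprints. The scavenger receptor Cd36 rose by 4.82 ± 0.21 (adjusted p = 6.2e-11) and 4.34 ± 0.28 (adjusted p = 6.6e-09), and Cd14 by 2.56 ± 0.18 (adjusted p = 1.1e-05) and 2.88 ± 0.22 (adjusted p = 3.9e-05). Of 18 ATF4 targets, 13 rose and 1 fell in input, and 15 rose and 1 fell in footprints, with Chac1 at 3.26 ± 0.26 and 3.21 ± 0.27. Among endoplasmic reticulum chaperones 13 rose and 1 fell in input (median 0.45) and 9 rose and 1 fell in footprints (median 0.24), with Hspa5 at 1.62 ± 0.092 in input (adjusted p = 3.4e-09). Actb rose by 1.10 ± 0.079 in input (adjusted p = 3.6e-08). Gapdh rose by 0.29 ± 0.089 (adjusted p = 0.014), a call lost with scaling by total counts (0.12, adjusted p = 0.26).

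Falls at 16 h took in proliferation, histone and mitochondrial genes. All 53 histone mRNAs fell in both materials (medians of -2.75 and -2.64), also adjusted over the list alone; many histone genes are near-identical, so the split of reads among them is uncertain. Of 32 cell cycle genes, 30 fell in input and 29 in footprints, among them the proliferation marker Mki67 (-2.48 ± 0.11, adjusted p = 2.6e-09, and -2.34 ± 0.12, adjusted p = 2.8e-10) and the mitotic motor Kif11 (-2.32 ± 0.1, adjusted p = 4.9e-10, and -2.30 ± 0.11, adjusted p = 2.2e-10). Nuclear-encoded oxidative phosphorylation mRNAs fell in 59 of 72 cases in input and 53 in footprints, by a median of -0.54 and -0.49 (camera adjusted p = 7e-07 and 5.6e-06; 0.54 and 0.13 with an estimated correlation). Of 13 mitochondrially encoded mRNAs, 8 fell in input (median -0.96, camera adjusted p = 0.002, and 0.56 with an estimated correlation) and 1 in footprints. Large falls were in Ranbp3l, 74.4-fold below untreated in input and 50.4-fold in footprints, and the surface protein Cd101, 34.8-fold and 33.2-fold below. Footprints on ribosomal protein mRNAs fell in 47 of 72 cases at 16 h, by a median of -0.32 (camera adjusted p = 0.0021, and 0.78 with an estimated correlation). Their median ratio to untreated (-0.29) lay at percentile 44.8 of random lists matched on mean expression, so equally abundant mRNAs fell about as much. In all, 2692 genes rose and 2577 fell in input (5269), and 2476 rose and 2342 fell in footprints (4818). The balance turned with total counts, to 2107 up and 3376 down in input and 2104 up and 2798 down in footprints.

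The 16 h test of density asked where footprints and input had parted. Density fell most on Irf7, the transcription factor that amplifies the interferon response (chromosome 7, 141262706 to 141266481, GRCm38), by 3.67 ± 0.48 on the log2 scale (adjusted p = 0.0026). Irf7 mRNA stood at 212-fold of untreated in input (147 to 319) but at 26.2-fold in footprints (12.4 to 66, on 7 untreated counts). Density on Fth1 (chromosome 19, 9980598 to 9985098) fell by 1.96 ± 0.18 (adjusted p = 1.2e-05), with input at 4.67-fold (4.58 to 4.76) and footprints at 1.07-fold (1.03 to 1.11). Rises were seen on the stress regulator Atf4 (1.59 ± 0.16, adjusted p = 1.3e-05), the mitochondrial carrier Ucp2 (1.89 ± 0.25, adjusted p = 0.0052), the cystine transporter Slc7a11 (1.12 ± 0.21, adjusted p = 0.012) and the cytochrome oxidase subunit Cox5b (1.19 ± 0.2, adjusted p = 0.0066). Ucp2 input was at 1.03-fold (0.955 to 1.11) and its footprints at 3.67-fold (3.27 to 4.13). Atf5, a relative of Atf4, rose by 1.63 ± 0.35 (adjusted p = 0.031), a call lost without the 15 min or the 75 min pair (adjusted p = 0.051 each). Nr4a1 (3.80 ± 0.61, adjusted p = 0.0026), Zc3h12a (2.61 ± 0.49, adjusted p = 0.012), Nfkbiz (1.63 ± 0.27, adjusted p = 0.0052) and Nfkbid (1.44 ± 0.26, adjusted p = 0.011) rose as well; with a linear time term these 4 stood at 0.27, 1.17, 0.55 and 0.81 and lost their calls (adjusted p = 0.96, 0.53, 0.63 and 0.42). Without the time-point block the calls of Nr4a1, Nfkbiz, Nfkbid, Atf4 and Atf5 were lost (adjusted p = 0.7, 0.87, 0.82, 0.18 and 0.068), and with DESeq2 those of Atf5 and Slc7a11 (0.73 and 0.13). That of Atf5 was also lost with library sizes without mitochondrially encoded and the most abundant genes (0.052). The rises of Nr4a1, Zc3h12a, Nfkbiz and Nfkbid share their fitted value at 0 min with those within 90 min, so they are not independent of them. The 16 h test was not run without the untreated pair. Altogether 36 genes rose and 12 fell (48), but 19 rose and 27 fell with library sizes without mitochondrially encoded and the 20 most abundant genes. Between 26 (without the 15 min pair) and 143 (without the 30 min pair) were called on leaving out single time points from 15 to 90 min.

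**Figure D3:**
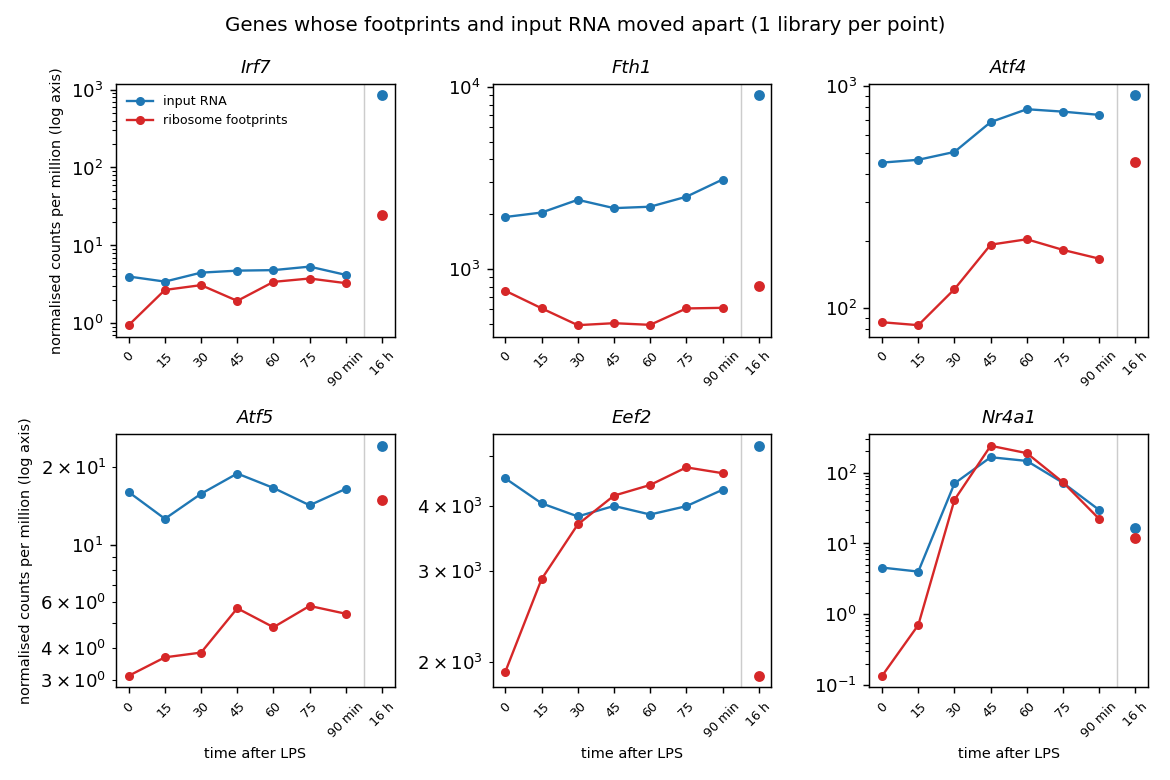
Normalised CPM (log axis) of 6 genes against time after LPS, in input and in footprints, with 1 library per point. The log2 ratio of footprints to input is not plotted. For Irf7 it went from -1.87 in untreated cells to -4.81 at 16 h. For Eef2 it went from -1.04 to 0.30 at 90 min and -1.20 at 16 h.

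The mean density level over all time points differed widely between mRNAs. Among the highest levels were those on the histone Hist1h4n (3.84 ± 0.11, adjusted p = 1.7e-19), the immunophilin Fkbp1a (3.54 ± 0.059, adjusted p = 1.3e-21) and the proton pump subunit Atp6v0c (3.50 ± 0.059, adjusted p = 1.2e-21). Among the lowest were the cytolinker Dst (-4.33 ± 0.26, adjusted p = 3.9e-07), the Ras regulator Nf1 (-4.08 ± 0.1, adjusted p = 1e-17) and the ferritin light chain Ftl1 (-3.99 ± 0.16, adjusted p = 4.7e-18), of whose coding 29-mers only 4.2% occur in no other annotated transcript, so reads shared with copies or lost may bear on its value. All 13 mitochondrially encoded mRNAs had few footprints per input read (median -2.84). Capture of mitochondrial ribosomes in the monosomal fractions was not tested, so that value need not reflect translation. Of 72 nuclear-encoded oxidative phosphorylation mRNAs, 68 were high (median 0.75). Histone mRNAs were high in 49 of 53 cases. The level fell with coding length across 9123 genes (Spearman correlation -0.50) and was not adjusted for it, so the high levels on these short coding sequences and the low ones on the long Dst and Nf1 run with that trend. The stress regulators Ppp1r15a (-3.59 ± 0.24, adjusted p = 1.3e-06) and Atf4 (-1.76 ± 0.17, adjusted p = 2.2e-05) were low. In all, 4150 genes lay above and 3951 below the typical gene (8101); with total counts the balance turned, to 3056 above and 4800 below, as it did among the 3920 genes past a 1.5-fold minimum (1776 and 2144). The features over which reads were counted are not given in the sources used here, so a level can depend on untranslated parts of the mRNA.

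Of the remaining lists, heat shock genes rose in 4 of 11 cases in input and 3 in footprints within 90 min, among them the co-chaperone Bag3 in footprints (1.05 ± 0.13, adjusted p = 8.6e-05). Of 4 tested osteoclast markers, the regulator Nfatc1 fell in footprints within 90 min (-1.42 ± 0.16, adjusted p = 1e-05; -0.79 without the 90 min library), a call lost with the square root of time (-1.09, adjusted p = 0.24), and the fusion protein Dcstamp rose at 16 h in input (1.92 ± 0.21, adjusted p = 2.6e-06). The only lymphocyte marker tested, Cd79b, did not pass the test in either material, and no fibroblast marker, epithelial marker or noncoding RNA on the lists passed the count filter. Of 114 tests of lists, 62 passed camera at the preset correlation and 17 with an estimated correlation. Those 17 were, within 90 min, feedback regulators, cytokines and chemokines in input and footprints, ATF4 targets in input, late effectors in footprints, and ribosomal proteins and feedback regulators in density. At 16 h they were cytokines, interferon-stimulated genes and late effectors in both materials, and cell cycle genes in footprints.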

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

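Every test of an explanation in this part was chosen after the result was seen, except the one on the loading of strongly induced mRNAs for Fth1.

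Footprints and input took different curves over 0 to 90 min for 122 genes, and differed in their change at 16 h for 48, by the interaction test of the density model. A further signal came from genes outside the tested set: 66 genes had at least 30 counts at 16 h and at most 3 in untreated cells in both materials. Lcn2 (an iron-scavenging protein) went from 1 to 2343 counts in input and from 0 to 4370 in footprints, Il6 from 0 to 968 and from 0 to 1519, and Nos2 (inducible nitric oxide synthase) from 2 to 849 and from 0 to 1695. Of the 66, 6 were on the interferon list, 4 each on the cytokine and late effector lists and 3 on the chemokine list; the fibroblast marker Lum went from 0 to 37 and from 0 to 68. Each rests on 1 library per material and was not tested.

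The density rise on ribosomal protein and other TOP mRNAs within 90 min was weighed against 4 technical explanations. For the rise in footprints, an error of the untreated library alone is argued against by the fit without it. There 55 of 72 ribosomal protein mRNAs were still called up over 15 to 90 min. In density none were called without the untreated pair, at a median excursion of 0.46. The size of the early density step thus rests on that pair, and for density this explanation stays open. Short or abundant coding sequences gave a median of at most 0.11 in 10000 matched random lists, against 0.81 for ribosomal proteins at 90 min. Shared reads are argued against as the whole cause by members with at least 70% unique 29-mers, of which 8 of 13 were called up at a median of 0.60; members with fewer unique 29-mers rose more often and further (70 of 82, median 0.92), so shared reads may add to the size. Scaling is argued against by the 63 ribosomal protein mRNAs called up under the least favourable of 4 other scalings. A regulated release of TOP mRNAs onto ribosomes may explain the pattern; it remains a hypothesis, since it was found and tested on the same data.

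The fall of Irf7 density at 16 h was not shared by interferon-stimulated mRNAs in general, since the lowest of the other 23 stood at -0.52 and their median at 0.07. Shared reads are argued against by 100% of Irf7's coding 29-mers occurring in no other annotated transcript; an antisense overlap with another gene covered 45 bases against a coding length of 1374. Repression through Oasl1, a protein described as a translational repressor of Irf7, could be a candidate explanation, with Oasl1 footprints at 60.9-fold of untreated at 16 h. Within 90 min Oasl1 footprints had already risen (3.29 ± 0.34, adjusted p = 0.0032; 0.079 with the square root of time), while no fall of Irf7 density was called (0.89 ± 0.53, adjusted p = 0.79; -0.39 without the untreated pair). Those values do not go with the explanation, but Irf7 counts were then few and protein was not measured. It stays open, also because Oasl1 is itself interferon-stimulated and a single late time point ties the pair together.

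The fall of Fth1 density at 16 h was not what strongly induced mRNAs did in general. Of 354 genes whose input rose at least as much, 2.26% fell by more than 1 (log2) in density, and their median change was 0.04. Reads shared with copies are argued against as the whole cause by 75.2% unique coding 29-mers. Control through iron-responsive elements, carried by both ferritin mRNAs, could explain it; Ftl1, named here after its value was seen, stood at -1.11, which did not pass the test, and only 4.2% of its coding 29-mers were unique, which leaves this open.

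The counts within 90 min were compared with those under other orders of the time points, and the level count with swaps of material. In input and footprints the calls went with the time order, but any steady drift along the series would do the same. Input and footprints were prepared differently, so swaps were bound to call fewer genes in the level test. Of 100 orders of the time points 1 gave as many calls as the real one in input within 90 min (2579, highest other 826) and 1 in footprints (2077, highest other 679), that 1 being the real order. In density 2 of 100 did, and the other order gave more calls than the real one (143 against 122), so that count does not stand above every other order. For the density level, 1 of 100 swaps of input and footprints within time points gave as many (8101, highest other 5305).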

How the results depend on the processing

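Of the alternatives, scaling by total counts and the cubic curve were chosen after the data were seen. Each group has only 1 library, so time points could not be compared across paired replicates. Input and footprints of a lysate were paired by the time-point block of the density models. Without that block 107 genes in place of 122 were called within 90 min. Input within 90 min gave 2579 genes, against 1677 with DESeq2 and 1406 with the square root of time. Footprints within 90 min gave 2077, against 821 with the square root of time and 3541 with total counts (723 up, 2818 down). Density within 90 min gave 122, against 56 with a linear term. Density at 16 h gave 48, against 25 with DESeq2 and 27 with no time-point block. The density level gave 8101, against 3920 with a 1.5-fold minimum, which asks for larger effects, and list tests 62, against 17 with an estimated correlation, which asks for more than a preset one. For the other changes the cause was not tested. On leaving out single time points the counts ranged from 1694 (without 90 min) to 2958 in input and 1395 to 2540 in footprints within 90 min. They ranged from 5 (without untreated) to 328 (without 30 min) for density within 90 min and from 26 (without 15 min) to 143 (without 30 min) for density at 16 h, with 30 each without 60 or 75 min. The 16 h comparisons were not run without the untreated or 16 h libraries. The other ranges were 4999 to 5580 and 4417 to 5109 for input and footprints at 16 h, 7949 to 8070 for the level and 59 to 63 for lists. For lists without the untreated or the 16 h libraries, the 16 h contrasts were kept from the full fit. Total counts shifted the median gene by -0.132 in input, -0.257 in footprints and -0.115 in density within 90 min, -0.162 in input at 16 h and -0.218 in the level. The share of rises then went from 56.1% to 33.6%, 58.1% to 20.4%, 89.3% to 62.8%, 51.1% to 38.4% and 51.2% to 38.9%. DESeq2 gave 68.7% for footprints within 90 min, and 64% against 75% for density at 16 h. Library sizes without mitochondrially encoded and the 20 most abundant genes gave 41.3% for density at 16 h (shift -0.146), and put Slc7a1 density at 0 in place of 0.14. Gapdh input within 90 min (-0.04) changed sign with a linear term (0.01), the square root of time (0.02), a cubic curve (0.1) and without the 15 or 60 min library (range -0.11 to 0.04). DESeq2 called Tnf, Nfkbia, Zfp36, Dusp1 and Ier3 in input and footprints, and Nfkbid in input, where edgeR had not. Over the named genes, 945 values under other settings kept direction and side of the threshold, 50 fell short of it, 13 passed it and 4 changed sign; on leaving out time points 830 kept both, 37 fell short, 2 passed and 3 changed sign, among them Irf7 density within 90 min (0.89, range -0.39 without untreated to 1.39 without 15 min). Depth was not varied; on simulated data of this depth and design, 1.5-fold changes in density were found for 17.9% of genes within 90 min and 23.9% at 16 h.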

Other observations

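All tests of explanations in this part were chosen after the results were seen.

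Among genes not described above, the mRNA of Plk2, a stress-induced kinase, stood at 856-fold of untreated in input at 16 h (292 to 4150, on 3 untreated counts) and at 674-fold in footprints (263 to 2480, on 4). Ifi202b, an interferon-induced DNA sensor, rose in input by 9.55 ± 0.4 (adjusted p = 5.3e-13). The chemokine Ccl3 stood at 94.5-fold in input and 160-fold in footprints at 16 h. Dst density rose by 1.58 ± 0.24 (adjusted p = 0.0026) at 16 h, with input at 2.21-fold and footprints at 6.09-fold. The scavenger receptor Msr1 rose by 2.29 ± 0.078 in input (adjusted p = 2.5e-11) and 2.13 ± 0.12 in footprints (adjusted p = 6.1e-10), while the lysosomal protein Laptm5 fell by 1.51 ± 0.18 in footprints (adjusted p = 4.9e-05).

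Atf4 and Atf5 mRNAs carry upstream reading frames, and both gained density at 16 h. A hypothesis was that other mRNAs with regulatory upstream frames would do so too. The median change of 7 others was 0.62, at percentile 100 among 10000 lists matched on coding length and mean count, and 6 of the 7 lay above 0: Ppp1r15a 1.55, Ifrd1 0.91, Ibtk 0.64, Slc35a4 0.62, Ppp1r15b 0.48 and Slc7a1 0.14. Eprs stood at -0.23, and only Ifrd1 passed the test, a call lost without the 75 min pair (0.90, adjusted p = 0.05), with no time-point block (adjusted p = 0.77), with total counts (0.068) and with library sizes without mitochondrially encoded and the most abundant genes (0.061). Ppp1r15a passed without the 15 min pair (1.99, adjusted p = 0.044) and with a linear time term (1.80, adjusted p = 0.00091) and Ibtk without the 30 min pair (0.62, adjusted p = 0.013). The random lists were not matched on density level. Of the 36 density rises at 16 h, 31 were on mRNAs called below the typical gene in level, against 14.9 expected if unrelated. The percentile therefore cannot tell upstream frames apart from a low level. A stress response acting on translation at 16 h may link the mRNAs with upstream frames, which these libraries alone do not settle.

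Of the genes outside the ribosomal protein and other TOP lists, 30 rose in density within 90 min. Whether they include further TOP mRNAs was tested on annotated 5′ ends: 3 of 26 (11.5%) began with a TOP start, against 450 of 8951 other genes (5.03%; odds ratio 2.46, Fisher's exact test, one-sided p = 0.14). The test could have missed them, since only 20 of 72 ribosomal protein genes had an annotated TOP start.

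The density level fell with coding length, from a median of 0.58 among the shortest coding sequences (median 600 nt) to -0.54 among the longest (median 3165 nt), with a Spearman correlation of -0.50 across 9123 genes, which are not independent replicates. Counting of reads over whole transcripts could lower the level of mRNAs with long untranslated parts. In a joint fit the slope on the coding fraction was 0.11 (SE 0.013) and on coding length -0.47 (SE 0.0091), so the fraction does not account for the trend with length.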
